A study of Mus musculus with 6 samples.

How the data were processed

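The series measured polyadenylated RNA of primary mouse cholangiocytes from WT and PLD animals 3 months after tamoxifen, with 3 libraries per group. Per the labels' protocols, livers were perfused and digested with collagenase, parenchymal cells were removed, the biliary tree was digested further, and cells were taken with an EpCAM antibody on magnetic beads. Purity was judged by CK19 staining, and sequencing used the BGISEQ-500 platform.

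The deposited values are raw read counts per gene, 1 table per library, and per the file headers the authors made them with featureCounts 1.6.0 on the GENCODE vM25 annotation of mm10. The command in the file headers names no option for strand, paired ends, multi-mapping reads or overlapping genes. Without a strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads that fit several near-identical genes are left out by the program's default. Values of ribosomal protein genes and Gapdh, which have many processed copies, of the Mup, Serpina1, Hspa1, Saa, Gsta, Pcdhb and H2 families and of mitochondrial genes are therefore uncertain. STAR 2.7.4a, SAMtools 1.12 and DESeq2 1.26.0 are also named, per the submitters' processing notes, without their settings. Strandedness of the kit and read length are not given in the sources used here.

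The tables hold 55401 gene IDs with identical gene models. Symbols came from GENCODE vM21, matched on the ID without its version for 55141 IDs, and the 260 others kept their ID. Coordinates are those of the files, from the lowest exon start to the highest exon end. Library totals ran from 15768561 to 16710548 counted reads, so 3 counts, the smallest amount taken as a floor, correspond to between 0.180 and 0.190 CPM. Intervals on ratios of reads are 95% exact binomial intervals and cover counting error only, as molecular identifiers are not mentioned per the labels' protocols.

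Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group kept 15334 genes, which held 99.8% of the reads of the library with the lowest share, and TMM factors (0.922 to 1.04) scaled the libraries. The quasi-likelihood F test compared PLD with WT without other covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are TMM-normalised, and the biological coefficient of variation was 0.196. A total of 44 gene lists were fixed before the data were examined, 28 on the biology of cholangiocytes and cysts, 11 on other cell types and 5 on sex, handling and RNA quality. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided, adjusted over 42 lists. Camera with an estimated correlation and fry were run beside it.

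The genes named were fixed by rule before the data were examined. The rule took the 10 genes higher and the 10 lower in PLD with the largest log2 fold change, and the 5 of each direction with the smallest p. These needed a mean log2 CPM of at least 3, a symbol that is not of a predicted gene, and PLD values all above or all below the WT values. The rule also took every polycystic disease gene and, of each other list, up to 4 genes with the smallest p. Other list members are printed as examples chosen after their values were seen.

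Replicates of a group were compared with a chi-square statistic over genes with at least 50 reads in a pair. It lay between 9.72 and 63.9 per degree of freedom, so no pair agreed within sampling noise. The functions were tested on simulated data with the real means, library sizes and spread of the 15334 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The test recovered 53.1% of the 2-fold and 89.9% of the 4-fold changes, 0 with the wrong direction, and 4.73% of its calls were false. Far fewer genes changed there than in the data, so these shares do not give the recovery in the data.

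Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter on low counts, a filter of 1 CPM in 3 libraries, a robust fit, a replicate block, leaving out each library, and a minimum log2 fold change of 1. Alternatives added after seeing the data were a correction for gene length and a TREAT test of rises beyond the median of the cholangiocyte identity list. The length correction fits a loess trend (span 0.5) of each library's log2 CPM deviation on log2 gene length. It was run without centring, which shifted all genes, and then centred in each library, and both versions are given. All tests of explanations except the count of other splits were written after the results were seen. Tests on the immediate early genes and on Msln were run, seen and then dropped to keep to 3 patterns. The first asked whether the immediate early genes fell with endothelial RNA alone, and their median (-0.74) lay more than 1 log2 unit above the endothelial median (-3.45), the bound set against that explanation, though the result had been classed as open. That bound cannot decide the question, since genes that other cells also express would fall less than endothelial markers. In PLD the immediate early list stayed at a mean log2 CPM of 9.33 to 9.43, against 4.47 to 5.30 for the endothelial list. The second asked whether Msln rose with mesothelial cells, and the median of the other 8 mesothelial markers was -2.14 (-1.69 with Msln), which argued against that. The test on hepatocyte RNA first left out the 4 markers that rose, so it was replaced by the median of the whole list. The label rules for the endothelial and macrophage gap and for the endothelial range were settled after their values were seen. Figures were drawn with matplotlib 3.10.9.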

Results

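Polyadenylated RNA was sequenced from cholangiocytes, the epithelial cells that line the bile ducts, of wild-type (WT) mice and of mice with polycystic liver disease (PLD), 3 months after tamoxifen. Each group held 3 libraries. The cells came from perfused and digested livers and were collected with magnetic beads against the epithelial surface protein EpCAM. The libraries held between 15768561 and 16710548 counted reads, so depth was nearly equal across the groups. Replicates of a group correlated with Pearson r between 0.972 and 0.991 across genes on the log2 CPM scale, and libraries of different groups between 0.846 and 0.914. PLD replicate 1 correlated less with the other PLD libraries (r = 0.976 and 0.973) than these did with each other (r = 0.991). WT replicate 1 likewise correlated less with the other WT libraries (r = 0.972 and 0.980) than these did with each other (r = 0.988). The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. All 6 libraries had Y-linked reads (Ddx3y, 2509 to 3844 reads) and at most 10 reads of Xist.

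The comparison asked which transcripts differed between the EpCAM-selected WT and PLD preparations. Per 100 Epcam reads, the endothelial gene Pecam1 had 210 to 425 reads in WT and 4.50 to 10.3 in PLD. A fall in PLD may thus come from fewer endothelial or other non-epithelial cells or from the cholangiocytes, which was not separated. A rise may likewise come in part or whole from a higher share of epithelial cells, as Epcam itself was higher in PLD. Cholangiocyte identity genes were mostly higher in PLD, and Krt20, Psca, Anxa8 and Msln rose as well. Secretion and transport genes went both ways, with Aqp5 and Ano1 higher and Aqp1 and Cftr lower. All 23 endothelial markers and 21 of 26 fibroblast and stellate markers were lower in PLD. Genes of oxidative phosphorylation, ribosomal proteins and oxidative stress were mostly higher, and genes of Notch, YAP, cAMP and interferon signalling were mostly lower. The lists of mostly higher or lower genes named here passed camera with its preset correlation, and 0 of them passed with an estimated correlation (lowest adjusted p = 0.7345). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4136 genes were higher and 4357 lower in PLD among 15334 tested, which is 55.4% of the genes. The change was at least 2-fold for 1413 of the higher and 2775 of the lower genes, and at least 8-fold for 170 and 510. PLD and WT values did not overlap for 10145 genes (66.2%), where chance gives 10%. Of the changed genes 48.7% were higher, against 61.1% when a gene length trend was removed without centring, which shifted the median gene by 0.18 on the log2 scale.

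The genes linked to polycystic liver or kidney disease went both ways. Pkd1, which encodes the membrane protein polycystin-1 (ENSMUSG00000032855.6, mm10 chromosome 17, 24549834 to 24596508), fell from 198 ± 7.5 to 60.1 ± 14.7 CPM (mean ± SD, n = 3 libraries each). Its log2 fold change was -1.72 with a standard error (SE) of 0.17 (edgeR adjusted p = 2.10e-04). Lrp5, a Wnt co-receptor, fell from 372 ± 34.7 to 166 ± 14.3 CPM (log2 fold change -1.16 ± 0.12 SE). Pkd2, the partner channel of polycystin-1, rose by 0.50 ± 0.12, the glucosidase subunit gene Prkcsh by 0.58 ± 0.12 and the ciliary gene Cys1 by 0.95 ± 0.22 on the log2 scale. Sec61b rose by 0.64 ± 0.18 and Alg9 by 0.35 ± 0.13, and Sec63 fell by 0.27 ± 0.09, each close to the threshold (edgeR adjusted p = 0.0169, 0.0474 and 0.0278). The other 7 genes did not pass, among them Pkhd1 (log2 fold change -0.18), Ganab (0.19), Alg8 (-0.13), Dnajb11 (0.19), Dzip1l (-0.27) and Bicc1 (0.06). Of 15 polycystic disease genes 5 rose and 3 fell, with the same counts adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.844). Beside the falls of Pkd1 and Lrp5, the endothelial and fibroblast marker medians were -3.45 and -1.67. Which cells the lost Pkd1 and Lrp5 RNA came from was not tested. The cholangiocyte identity median was 1.41 in the same libraries, above the largest rise among the polycystic disease genes (0.95). Whether Pkd2, Prkcsh, Cys1 or the genes that did not pass changed within cholangiocytes was therefore not separated from cell composition. The labels do not name the gene targeted in the PLD mice. The Sec63, Sec61b and Alg9 calls were lost after a length correction (adjusted p = 0.386, 0.205 and 0.0595), and Sec63 changed sign to 0.08 when that correction was not centred.

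Cholangiocyte identity genes rose in PLD: 21 of 25 were higher, 22 adjusted over the list alone, with a median log2 fold change of 1.41 (camera adjusted p = 9.26e-07, and adjusted p = 0.7345 with an estimated correlation). The duct keratin Krt7 (ENSMUSG00000023039.17, chromosome 15, 101411043 to 101430313) rose from 79.6 ± 14.6 to 1022 ± 46.3 CPM, a log2 fold change of 3.68 ± 0.16 (edgeR adjusted p = 2.5e-05). Krt19 rose by 3.26 ± 0.25 and the tetraspanin Tspan8 by 2.76 ± 0.14 on the log2 scale. Epcam, the target of the bead selection, rose by 1.61 ± 0.24, from a mean of 355 to 1085 CPM. Foxj1 (0.01), Hnf4g (0.48), Onecut1 (-0.52) and Pdx1 (0.00) did not pass. In the same libraries the median of the endothelial markers was -3.45.

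The largest rises named here are those among genes with a mean log2 CPM of at least 3 that met the naming rule, and some genes below that level rose further. Krt20, a keratin of gut and bladder epithelium (ENSMUSG00000035775.2, chromosome 11, 99428403 to 99438150), rose from 2.45 ± 1.5 to 704 ± 490 CPM. Its log2 fold change was 8.16 ± 0.71 (edgeR adjusted p = 1.25e-04). PLD replicate 1 had 1269 CPM of Krt20 against 440.5 and 401.3 in the other PLD libraries, and without it the log2 fold change was 7.43. Psca, encoding prostate stem cell antigen, rose by 7.81 ± 0.31, the annexin Anxa8 by 7.50 ± 0.44 and the aldo-keto reductase Akr1b7 by 7.23 ± 0.60, or by 8.19 without WT replicate 1. Anxa8 (650 against 316 and 300 CPM) and Akr1b7 (404 against 199 and 199 CPM) were also highest in PLD replicate 1. Psca was lowest there (55.5 against 78.6 and 72.3 CPM). Msln, encoding mesothelin (ENSMUSG00000063011.7, chromosome 17, 25748613 to 25754378), rose from 17.2 ± 1.41 to 934 ± 210 CPM (log2 fold change 5.77 ± 0.21). The endothelin gene Edn3 (5.94), the Wnt ligand gene Wnt7a (5.43), the proton pump subunit gene Atp6v0a4 (5.40) and Scel (5.18) were also among the 10 largest by that rule. Lamb3, a chain of the basement membrane protein laminin-332, rose by 3.43 ± 0.12, and the cell cycle inhibitor gene Cdkn2b by 4.12 ± 0.18.

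**Figure D1:**
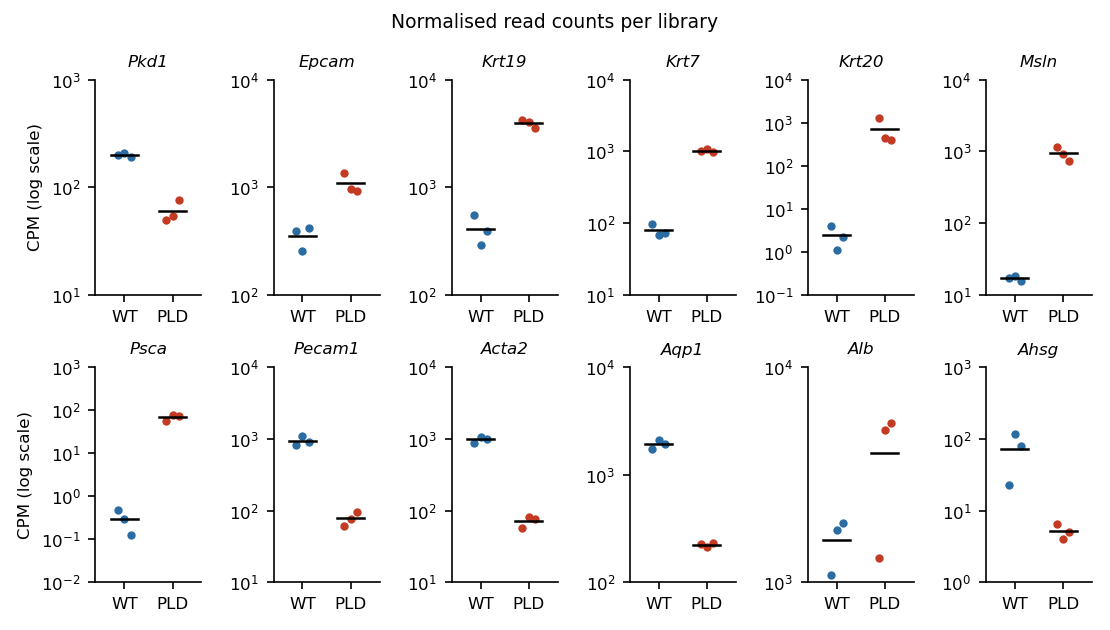
Normalised read counts (CPM, log scale) of 12 genes in each library, with WT in blue and PLD in red; each point is 1 of 3 libraries and the bar is the group mean. Krt7, Krt19, Krt20, Msln and Psca are higher in all 3 PLD libraries, Pkd1, Pecam1, Acta2, Aqp1 and Ahsg are lower, and Alb overlaps between the groups (1085 to 1888 CPM in WT and 1303 to 5512 CPM in PLD).

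Bile secretion and transport genes changed in both directions, 9 of 20 rising and 5 falling, with the same counts adjusted over the list alone (camera adjusted p = 0.426). The water channel gene Aqp1 fell from a mean of 1933 to 224 CPM (log2 fold change -3.11 ± 0.13, edgeR adjusted p = 2.5e-05), and another water channel gene, Aqp5, rose by 3.49 ± 0.46. The chloride channel gene Cftr fell by 2.24 ± 0.39, and Ano1, a calcium-gated chloride channel gene, rose by 2.56 ± 0.16. The bile acid transporter gene Slc10a2 rose by 2.49 ± 0.33 and the export pump gene Abcc3 by 2.29 ± 0.27. In the cAMP signalling list 17 of 25 genes fell and 2 rose, with 18 falling adjusted over the list alone (camera adjusted p = 8.75e-04, and adjusted p = 0.7345 with an estimated correlation). The adenylyl cyclase gene Adcy5 fell by 3.22 ± 0.38, Rapgef3, a cAMP-gated exchange factor gene, by 2.63 ± 0.15 and the phosphodiesterase gene Pde3a by 2.38 ± 0.17. The somatostatin receptor gene Sstr2 rose by 1.51 ± 0.31. Endothelial markers, with a median of -3.45, and fibroblast markers, with a median of -1.67, fell in the same libraries.

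Markers of endothelial cells fell without exception among the 23 tested, with the same count adjusted over the list alone and a median log2 fold change of -3.45 (camera adjusted p = 1.32e-11, and adjusted p = 0.7345 with an estimated correlation). Pecam1, an adhesion protein of endothelial cells, fell from a mean of 937 to 77.9 CPM (log2 fold change -3.59 ± 0.20, edgeR adjusted p = 3.7e-05). Vwf, encoding von Willebrand factor, fell by 4.07 ± 0.36, and Stab2 and Lyve1, markers of liver sinusoids, by 4.24 each. Of the fibroblast and stellate markers 21 of 26 fell, 23 adjusted over the list alone, and 1 rose (median -1.67, camera adjusted p = 3.66e-05, and adjusted p = 0.7468 with an estimated correlation). The smooth muscle actin gene Acta2 fell by 3.78 ± 0.18, Mgp, encoding matrix Gla protein, by 3.44 ± 0.13 and Reln by 3.56 ± 0.42, while Thy1 rose by 1.08 ± 0.19. The mean log2 CPM of the fibroblast list was 5.63 in PLD replicate 1, against 6.6 and 6.82 in the other PLD libraries and 7.90 to 8.41 in WT.

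Among genes with a mean log2 CPM of at least 3 that met the naming rule, Gria1 and Muc6 had the largest falls. The smooth muscle genes Actg2 and Cnn1 fell by 5.31 ± 0.26 and 5.30 ± 0.24 on the log2 scale. The matrix genes Hmcn2 and Cilp fell by 5.04 and 5.02 and the noncoding RNA gene Meg3 by 5.05 ± 0.15 (edgeR adjusted p = 1.9e-05). Slc26a10 (-4.87) and the potassium channel gene Kcna2 (-4.85) fell as well. The glutamate receptor gene Gria1 had 2 reads over the 3 PLD libraries and 851 over the WT libraries, a ratio of reads per total reads of 427 (95% exact binomial interval 118 to 3533, counting error only). Both PLD reads of Gria1 came from PLD replicate 3, and without that library the ratio has no finite value. The gastric-type mucin gene Muc6 fell by 5.94 ± 0.82 and the major urinary protein gene Mup3 by 5.47 ± 0.96. The Mup3 value depended on single libraries, with -6.86 without PLD replicate 3 and -4.68 without WT replicate 2. Slit3 fell by 3.69 ± 0.13, Fgd5 by 3.79 ± 0.15 and Abca8a by 2.61 ± 0.10. Pancreas, gut and gland markers as a list did not pass camera (adjusted p = 0.719), with 2 of 9 higher, Tff2 (3.21) and Tff3 (4.31), and 2 lower, Muc6 and Dclk1 (-1.72). Tff3 varied between the WT libraries (11.2, 0.236 and 0.865 CPM), and its log2 fold change was 7.21 without WT replicate 1.

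Hepatocyte markers mostly fell, 20 of 33 lower and 4 higher, 5 higher adjusted over the list alone (median -2.58, camera adjusted p = 0.0394, and adjusted p = 0.7468 with an estimated correlation). Ahsg, encoding the plasma protein fetuin-A, fell from a mean of 73.1 to 5.14 CPM (log2 fold change -3.83 ± 0.57, edgeR adjusted p = 0.0012), and the urea cycle gene Cps1 fell by 4.11 ± 0.62. Apob rose by 3.24 ± 0.34, Ambp by 1.87 ± 0.17, Cyp2e1 by 1.81 ± 0.25 and Ttr by 0.69 ± 0.10. Alb, the albumin gene, had a log2 fold change of 1.33 ± 0.50 and did not pass (edgeR adjusted p = 0.0537). The mean log2 CPM of the list ranged from 3.14 to 5.00 in the WT libraries and from 2.29 to 2.7 in PLD. The list call was lost without PLD replicate 1 (camera adjusted p = 0.0651) and without PLD replicate 2 (0.0766).

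Immune cell markers changed less uniformly. Among 23 macrophage markers 3 rose, 5 fell and 15 did not pass, with the same counts adjusted over the list alone (median -0.22, camera adjusted p = 0.423). Csf1r, a growth factor receptor gene, rose by 1.38 ± 0.18 and Cd14 by 1.72 ± 0.18. The mannose receptor gene Mrc1 fell by 3.12 ± 0.20, closer to the endothelial median (-3.45) than to the macrophage median. Of 13 dendritic cell markers 7 fell, the same adjusted over the list alone, including Clec9a (-3.54) and Zbtb46 (-2.10) (camera adjusted p = 0.0181, and adjusted p = 0.7468 with an estimated correlation). All 23 endothelial markers fell in the same libraries. Neutrophil markers fell for 3 of 8, led by Hdc (-3.80), and did not pass as a list (camera adjusted p = 0.107, and 0.0241 without PLD replicate 1 or 0.0314 without WT replicate 2). Of 10 B and plasma cell markers 4 rose, including Sdc1 (2.31) and Igkc (1.82), and 1 fell (camera adjusted p = 0.434). Sdc1 had 47957 reads over the PLD and 10253 over the WT libraries, against 1208 and 454 for Jchain. Which cells the Sdc1 reads came from was not tested. Among 8 T and NK cell markers Cd2 rose (1.59) and Trac fell (-0.99), neither of which passed adjusted over the list alone (camera adjusted p = 0.755). Ppbp (-2.33) and Itga2b (-0.81) fell among 3 tested erythroid and platelet markers. Mesothelial markers diverged: Msln, Upk1b (2.65) and Aldh1a2 (2.44) rose, and 5 of 9 fell, 6 adjusted over the list alone, including Wt1 (-2.75) and Muc16 (-4.12) (camera adjusted p = 0.426).

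**Figure D2:**
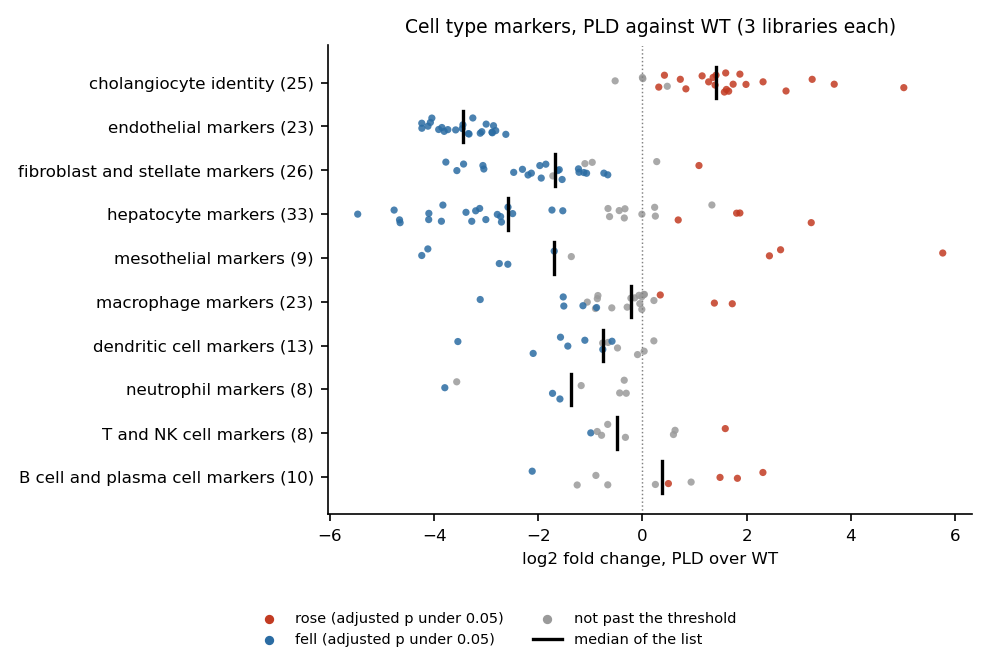
Log2 fold change (PLD over WT, horizontal axis) of each tested marker of 10 cell types, with the number tested in brackets; points are genes, red for higher, blue for lower and grey for not past the edgeR threshold, and the black bar is the list median. The endothelial markers all lie below 0 around -3.45, the cholangiocyte markers centre on 1.41 and the macrophage markers on -0.22.

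Growth factor response genes mostly rose, with 14 of 24 EGFR and MAPK response genes higher and 5 lower, the same adjusted over the list alone. Areg, an EGFR ligand gene, rose from 3.34 ± 1.9 to 119 ± 68.4 CPM (log2 fold change 5.15 ± 0.53, edgeR adjusted p = 2.5e-04). PLD replicate 1 was highest for Areg (198 CPM against 82.7 and 76.9) and for Dusp4 (472 CPM against 266 and 302). The phosphatase gene Dusp4 rose by 2.72 ± 0.28 and the urokinase receptor gene Plaur by 2.11 ± 0.27, while Spry1 fell by 1.42 ± 0.17 and Spry4 by 1.29 ± 0.10. The list did not pass camera (adjusted p = 0.0784, and adjusted p = 0.7345 with an estimated correlation). Camera called it without WT replicate 3 (adjusted p = 0.0432) and with the replicate block (adjusted p = 0.0473). Fry, which does not compare a list with other genes, called it as well (adjusted p = 0.0139). YAP target genes fell for 14 of 20 and rose for 4, with the same counts adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.7345 with an estimated correlation). The matricellular genes Ccn1 and Ccn2 fell by 2.49 ± 0.19 and 1.42 ± 0.12 and Lats2 by 1.75 ± 0.12, while F3, the tissue factor gene, rose by 1.35 ± 0.43. Endothelial markers had a median of -3.45 and fibroblast markers of -1.67 in these libraries.

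Notch pathway genes fell for 9 of 14 and rose for 0, with the same counts adjusted over the list alone (camera adjusted p = 0.0152, and adjusted p = 0.7345 with an estimated correlation). The receptor genes Notch3 and Notch1 fell by 3.31 ± 0.25 and 2.15 ± 0.13 and the ligand gene Dll4 by 2.11 ± 0.21, whereas Notch2 (0.24) and Jag1 (-0.28) did not pass. Hedgehog pathway genes fell for 7 of 13 and rose for 1, including Gas1 (-2.36), without passing camera (adjusted p = 0.121). Among 16 genes of the Wnt target list, which also holds the ligand genes Wnt7a and Wnt7b, 6 rose, 7 adjusted over the list alone, and 3 fell. Wnt7b (2.93) and Tcf7 (1.69) were higher and the secreted inhibitor genes Sfrp5 (-4.79) and Wif1 (-4.60) lower (camera adjusted p = 0.353). Epithelial to mesenchymal transition genes fell for 13 of 15, the same adjusted over the list alone, including Zeb2 (-1.86) and Vim (-1.96), and Fn1 rose (0.55). That list passed camera (adjusted p = 2.81e-04, and adjusted p = 0.7345 with an estimated correlation) and shares 6 of its genes with other lists, Acta2 and Tagln with the fibroblast markers. The extracellular matrix list split, with 14 of 26 falling, such as Col4a1 (-2.38), and 6 rising, among them the laminin-332 genes Lama3 (2.17) and Lamb3 and the protease gene Mmp7 (3.36) (camera adjusted p = 0.482). The endothelial and fibroblast marker medians stood at -3.45 and -1.67 beside these groups.

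Cell cycle genes mostly did not pass: 7 of 34 rose, 5 adjusted over the list alone, 1 fell and 26 did not pass (median 0.25, camera adjusted p = 0.371). Kif23 (2.56 ± 0.21) and the replication helicase gene Mcm6 (1.21 ± 0.13) rose and Cenpa fell by 1.56 ± 0.20, while the proliferation marker gene Mki67 did not pass (-0.58 ± 0.29). The mean log2 CPM of the list was 1.635 in PLD replicate 1, 2.48 and 2.57 in the other PLD libraries and 2.02 to 2.20 in WT. Without PLD replicate 1 the list was past the threshold (camera adjusted p = 0.00836), a setting not run with an estimated correlation. Senescence and p53 target genes rose for 11 of 20 and fell for 3, with the same counts adjusted over the list alone (camera adjusted p = 0.0246, and adjusted p = 0.7345 with an estimated correlation). Besides Cdkn2b, Perp rose by 2.47 ± 0.22 and the cell cycle inhibitor gene Cdkn1a by 1.27 ± 0.23 (edgeR adjusted p = 0.0026), while Sesn1 fell by 1.39 ± 0.14 and Plk2 by 1.13 ± 0.12. After the length correction that list lay just outside the threshold (camera adjusted p = 0.0517), with its median moving from 0.65 to 0.82. The cholangiocyte identity median was 1.41 beside it, and the endothelial and fibroblast medians were -3.45 and -1.67.

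Genes of oxidative stress and detoxification rose for 13 of 20, 15 adjusted over the list alone, and fell for 3 (median 0.69, camera adjusted p = 0.0034, and adjusted p = 0.7345 with an estimated correlation). The glutathione transferase gene Gsta4 rose from 23 to 680 CPM (log2 fold change 4.88 ± 0.68, edgeR adjusted p = 8.8e-04). Gclc, a subunit of the enzyme that limits glutathione synthesis, rose by 2.01 ± 0.25, the glutathione reductase gene Gsr by 1.39 ± 0.09 and Prdx1 by 1.49 ± 0.10. Nqo1 (-1.13), Slc7a11 (-1.01) and Gpx3 (-1.33) fell. In the same libraries the medians of the cholangiocyte identity, endothelial and fibroblast lists were 1.41, -3.45 and -1.67.

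Oxidative phosphorylation genes rose for 22 of 27, 23 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 2.61e-06, and adjusted p = 0.7345 with an estimated correlation). The respiratory chain genes Uqcrfs1 and Cox4i1 rose by 1.01 ± 0.11 and 1.14 ± 0.16. Ribosomal protein genes rose for 25 of 34, 26 adjusted over the list alone, and Rpl3, Rpl5 and Rpl11 fell (median 0.85, camera adjusted p = 3.70e-04, and adjusted p = 0.7468 with an estimated correlation). Rplp0 rose by 1.09 ± 0.15. Mitochondrially encoded genes rose for 4 of 7, the same adjusted over the list alone, such as mt-Nd6 (0.75), and did not pass as a list (camera adjusted p = 0.0784, and 0.0337 without PLD replicate 3). Shorter genes were higher in PLD across the data: the median log2 fold change was 0.40 in the shortest 10% of genes and -0.32 in the longest 10%. After a length correction the medians of the oxidative phosphorylation and ribosomal protein lists were 0.39 and 0.56, and 0 of 7 mitochondrially encoded genes rose. The medians of the cholangiocyte identity, endothelial and fibroblast lists were 1.41, -3.45 and -1.67 in these libraries.

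Other metabolic groups went both ways and none of them passed camera. Fatty acid oxidation and PPAR target genes rose for 8 of 23, 9 adjusted over the list alone, and fell for 4, with Pparg (1.69) and Acaa2 (0.86) higher and Cd36 (-3.73) lower (camera adjusted p = 0.416). Cholesterol and lipid synthesis genes fell for 9 of 24, including Sqle (-1.07) and Hmgcs1 (-0.71), while the regulator gene Srebf1 rose by 1.22 ± 0.14 (camera adjusted p = 0.152, and 0.0313 without WT replicate 2). Of 22 unfolded protein response genes 6 rose and 2 fell (camera adjusted p = 0.51), and the genes that rose included Trib3 (2.24), Asns (2.22) and Chac1 (2.35), known targets of the transcription factor ATF4. These 3 were highest in PLD replicate 1, and without it Trib3, Asns and Chac1 had log2 fold changes of 1.78, 1.75 and 1.75. Lysosome and autophagy genes rose for 8 of 25 and fell for 5, with Npc1 (1.21) and Sqstm1 (1.01) higher (camera adjusted p = 0.546). Hypoxia and VEGF genes rose for 7 of 20 and fell for 5, with the oxygen sensor gene Egln3 (2.55) and Vegfa (0.72) higher and the endothelial genes Flt1 (-3.33) and Angpt2 (-2.92) lower (camera adjusted p = 0.806).

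Interferon response genes fell for 14 of 25 and rose for 0, with the same counts adjusted over the list alone (median -0.54, camera adjusted p = 0.00231, and adjusted p = 0.7345 with an estimated correlation). Stat2 fell by 1.45 ± 0.11, Mx2 by 1.57 ± 0.18 and Ifi44 by 2.11 ± 0.30. Cytokine and chemokine genes fell for 13 of 30, such as Ccl7 (-1.47) and Il33 (-0.96), and rose for 4, 5 adjusted over the list alone, such as Cx3cl1 (1.11) and Cxcl16 (0.89) (camera adjusted p = 0.307). Antigen presentation genes fell for 4 of 18, including Tap2 (-0.74), and rose for 0 (camera adjusted p = 0.25, and 0.0415 without PLD replicate 3). Immediate early genes, which respond within minutes to stimulation, fell for 11 of 19 and rose for 0, with the same counts adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.7345 with an estimated correlation). Fos fell from 3369 to 2006 CPM and Egr1 from 4903 to 2780 CPM, log2 fold changes of -0.75 ± 0.17 and -0.82 ± 0.15 (edgeR adjusted p = 0.0073 and 0.0033). Klf2 fell by 2.04 ± 0.15 and Socs3 by 1.61 ± 0.12. Heat shock genes fell for 6 of 13, such as Hspb1 (-1.39), and Bag3 rose (0.35), without the list passing (camera adjusted p = 0.107). The immediate early and heat shock lists were fixed as checks of handling, and whether handling differed between the groups was not tested. Endothelial and dendritic cell markers had medians of -3.45 and -0.76 in the same libraries.

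Chromatin enzyme genes rose, fell or did not pass in each list, and no such list passed camera. Among 32 histone methylation enzyme genes 8 rose and 9 fell (camera adjusted p = 0.755), with the Polycomb genes Eed (0.62 ± 0.10) and Ezh2 (0.51 ± 0.12) and the demethylase gene Kdm1a (0.57 ± 0.09) higher, and Nsd1 (-0.93 ± 0.11), Kdm4c (-0.73 ± 0.09) and Kdm6b (-0.98 ± 0.13) lower. After the length correction 11 of these 32 genes rose and 4 fell, and the list median moved from -0.06 to 0.09. Of 27 histone acetylation and reader genes 7 rose, 5 adjusted over the list alone, and 4 fell, with Hdac11 (0.92) higher and Hdac7 (-0.91) and the weakly expressed Hdac9 (-2.38) lower (camera adjusted p = 0.844). DNA methylation and remodelling genes rose for 4 of 22 and fell for 7, with Smarcc1 (0.76) higher and Tet2 (-1.29), Chd7 (-1.23) and Dnmt3a (-1.01) lower (camera adjusted p = 0.353). Cilium assembly genes rose for 7 of 32, 6 adjusted over the list alone, and fell for 6, with Ift46 (0.87) and Kif3a (0.70) higher and Tulp3 (-1.11) and Arl13b (-0.86) lower (camera adjusted p = 0.792). Motile cilia genes rose for 2 of 13 and fell for 4, including the dynein gene Dnah5 (-3.04) (camera adjusted p = 0.376). Beside these groups the cholangiocyte identity, endothelial and fibroblast medians were 1.41, -3.45 and -1.67. Whether chromatin or cilium genes changed within cholangiocytes was not tested. Among 4 tested sex-linked genes Ddx3y (-0.39) and Kdm5d (-0.42) fell. The Kdm5d call was lost after the length correction (adjusted p = 0.678), and its sign turned (0.11) when that was not centred.

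**Figure D3:**
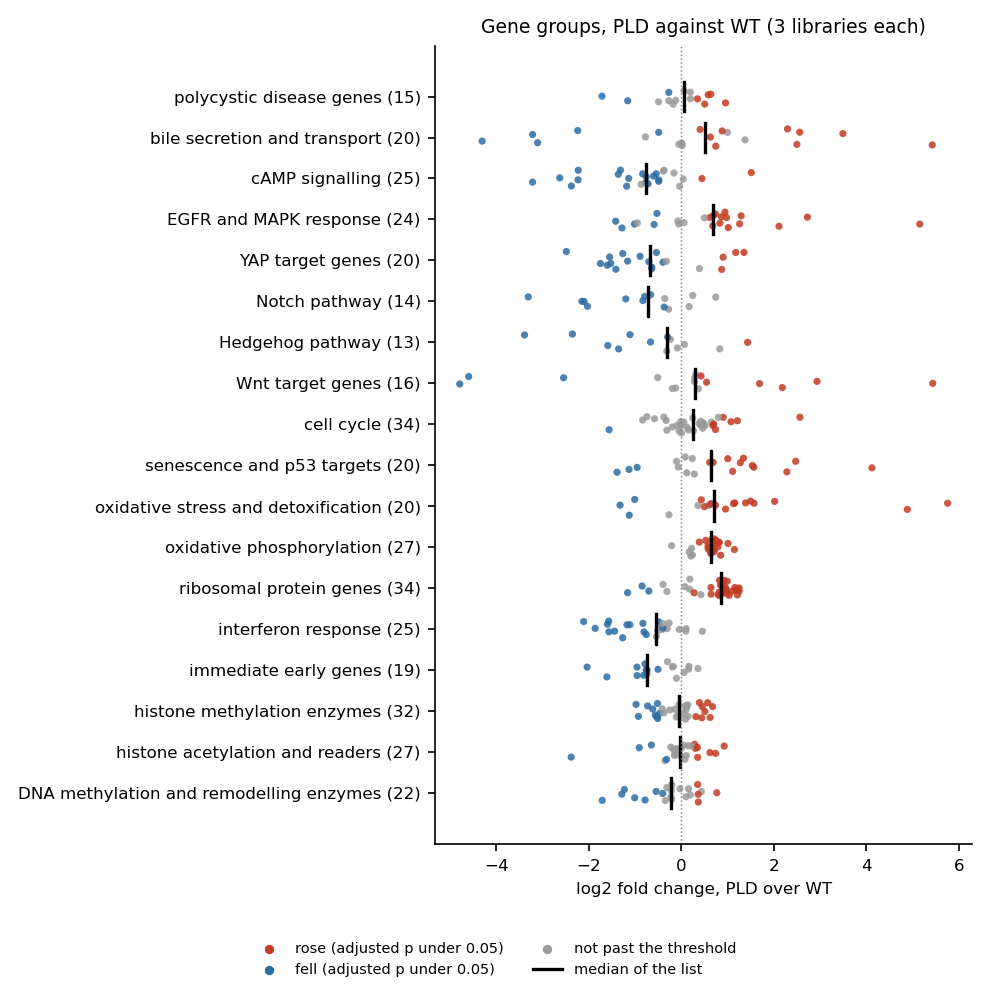
Log2 fold change (PLD over WT, horizontal axis) of each tested member of 18 gene groups, with the number tested in brackets; points are genes, red for higher, blue for lower and grey for not past the edgeR threshold, and the black bar is the list median. Oxidative phosphorylation and ribosomal protein genes cluster around 0.65 and 0.85, Notch and interferon genes centre on -0.73 and -0.54, and the medians of the chromatin enzyme lists lie between -0.22 and -0.03.

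Of 44 lists, 42 had at least 5 tested genes, and camera with its preset correlation of 0.01 called 5 higher and 10 lower. With an estimated correlation 0 of the 42 passed, while fry, which tests whether the genes of a list move on balance one way, called 23. With the correlation estimated from 6 libraries, the endothelial list, lower for 23 of 23 genes, had an unadjusted camera p of 0.0985. A list that failed at that setting is therefore not shown to be unchanged. Fry, but not camera without a block on all libraries, called the Hedgehog, hypoxia, motile cilia, DNA methylation, B cell, neutrophil, heat shock, mitochondrially encoded and EGFR lists, and fry did not call the hepatocyte list. Counts adjusted over the list alone equalled those over all genes in 29 of the 44 lists and differed by at most 2 genes in the other 15.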

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

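The length corrections and the TREAT test were chosen after seeing the data, and the other alternatives before the data were examined. Counts of genes and lists stayed within 1.5 times those reported, with the exceptions given here. Requiring an absolute log2 fold change of at least 1 left 1413 higher and 2775 lower genes, because this adds a minimum size, and 332 genes rose beyond the identity-list median by TREAT for the same reason. Of the lists, 0 passed with an estimated correlation and 23 by fry, against 15; fry does not compare a list with other genes. The hypoxia and VEGF list changed direction under fry (adjusted p = 0.0493), where its mean (-0.07) is below 0 and its median (0.11) above. Without centring, the length correction gave 5443 higher and 3471 lower genes (61.1% higher), and turned Sec63 (0.0821), Tcf4 (0.17) and Kdm5d (0.11) from lower to a value above 0 that did not pass. It shifted the median gene by 0.18, and the length fit moved these 3 genes further than that. With centring it gave 4081 and 4175 genes, and the same 3 stayed below 0 without passing.

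Leaving out each library in turn gave 3173 to 4183 higher genes, 3626 to 4562 lower genes and 14 to 17 lists. Of 190 named genes past the threshold, 172 stayed past it with the same direction under every alternative run gene by gene, which leaves out the minimum log2 fold change and TREAT. Of the 15 called lists, 13 stayed past the threshold under every alternative run on lists other than the estimated correlation; DESeq2, limma-voom, no filter and the robust fit were not run on lists. The hepatocyte list was lost without PLD replicate 1 (0.0651), without PLD replicate 2 (0.0766) and by fry (0.178), and the senescence list after length correction (0.0517, or 0.0777 without centring); the cause was not tested. A replicate block gave 3920 higher and 4242 lower genes and 16 lists, the added list being EGFR and MAPK response (0.0473). Deviations of same-numbered libraries correlated at 0.156, 0.0363 and 0.0613, and PLD replicates 2 and 3 correlated better with the WT library of the other number (0.122 and 0.099), so the numbers are not taken to pair the samples. With 3 simulated libraries per group at these totals and this spread, 53.1% of 2-fold changes were recovered. Only 100 genes changed 2-fold and 100 changed 4-fold there, against 8493 genes past the threshold in the data. The adjusted threshold is stricter when fewer genes change, so this share does not give the power of the real comparison.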

Other observations

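The protocadherin, collagen, keratin and other families below, Esr1 and all tests of explanations were chosen after the results were seen, except the count of other splits of the libraries, and the rules that decide what a value argues against were settled in part after the values were seen.

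A scan of 237 gene families defined by a shared symbol stem, each with at least 8 tested genes, found 28 past camera's threshold and 0 with an estimated correlation. All 19 tested genes of the clustered protocadherin family Pcdhb, neuronal-type adhesion proteins encoded side by side, were lower in PLD (median log2 fold change -2.02, camera adjusted p = 5.01e-06, and adjusted p = 0.704 with an estimated correlation). Pcdhb14 fell from 11.6 to 2.37 CPM and Pcdhb17 from 12.2 to 3.03 CPM, beside endothelial and fibroblast marker medians of -3.45 and -1.67. Genes with the stem Col, all but Col4a3bp collagens, fell for 27 of 34 and rose for 3 (median -1.72, camera adjusted p = 4.52e-04, and adjusted p = 0.704 with an estimated correlation). Keratin genes, with 1 pseudogene among them, rose for 14 of 16 and fell for 0 (median 1.57, camera adjusted p = 4.52e-04, and adjusted p = 0.704 with an estimated correlation), among them Krt23 (2.55) and Krt15 (2.84). Aldo-keto reductase genes (Akr) rose for 10 of 14 and fell for 1, and RNA polymerase subunit genes (Polr) rose for 19 of 28 and fell for 0, with medians of 1.02 and 0.48 (camera adjusted p = 0.00904 and 4.52e-04, and adjusted p = 0.704 each with an estimated correlation).

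Among nuclear receptor genes, Esr1, encoding oestrogen receptor alpha, rose from 21.7 to 687 CPM (log2 fold change 4.98 ± 0.30, edgeR adjusted p = 4.11e-05), with all 3 PLD libraries above the WT libraries. All 6 libraries carried Y-linked reads.

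Endothelial genes were lower and epithelial genes higher in PLD. A lower share of all other cells alike is argued against, since the endothelial median lay 3.23 below the macrophage median (difference -3.23, SDs of the members 0.505 and 0.987). A higher share of cholangiocytes alone is argued against for part of the rise: 8.03% of the higher genes rose beyond the identity-list median of 1.41, and Krt7 had 74.4 to 110 reads per 100 Epcam reads in PLD against 17.7 to 27.2 in WT, although that median includes genes that other cells express, such as Sox4, and so may understate the share. Fewer endothelial cells in the PLD preparations stays open and may account for the fall of endothelial genes, as all 23 markers, 1 of them shared with another list, fell within 1.61 log2 units of each other. Preparation and genotype changed together, so whether such a difference arose in the animals or during isolation and EpCAM selection was not tested.

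Apob, Ambp, Cyp2e1 and Ttr were higher in PLD. Hepatocyte RNA carried into the PLD preparations is argued against, since all 33 tested hepatocyte markers, these 4 included, had a median log2 fold change of -2.58 and 20 of them fell. This test replaced a median without these 4 genes, which had been chosen because they rose. Higher expression of these genes in PLD cholangiocytes could be a candidate explanation and was not tested.

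Ribosomal protein and oxidative phosphorylation genes were higher in PLD, where short genes in general were higher (Spearman correlation across genes of log2 fold change with length -0.195). The trend with gene length as the whole cause is argued against, since the smaller of both list medians stayed at 0.39 after correction. Both lists stayed past the threshold of camera with its preset correlation (adjusted p = 0.00791 and 2.25e-04). With an estimated correlation neither passed before correction (camera adjusted p = 0.7468 and 0.7345), and that setting was not run after correction. Gene length counts all annotated exons of a gene (list medians 1918.5 and 2178 bases) and can exceed the length of the expressed transcript. A trend with transcript length was not tested and stays open. Part of the rise moved with length, as the medians were 0.85 and 0.65 before correction and 0.56 and 0.39 after it. A change in these genes with the PLD genotype may remain and was not tested apart from the change in cell composition.

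Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, gave 8493 genes past the threshold, and the highest of the others gave 0. With 10 splits the share cannot fall below 0.1, so the splits are too few to reach 0.05.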
